A study of Cucumis sativus with 6 samples.

How the data were processed

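Phloem was collected by laser microdissection, in which a laser isolates chosen cells from thin sections of fixed tissue, from the pedicle (the stem that bears the flower and fruit), the stalk and the fruit of cucumber inbred line 9930, 3 days after anthesis (flower opening). Per the labels' protocols, total RNA was extracted from the dissected cells, amplified over successive rounds of antisense RNA synthesis and made into poly(A)-selected Illumina libraries. Each of the 3 organs has 2 libraries, which the series' design text calls biological replicates. The labels do not say how pedicle and stalk were delimited, nor which libraries were prepared on the same day.

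TopHat and HTSeq are named in the submitters' processing notes; their versions, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table of 15720 genes with a whole-number expression score, called TPTM, for each library. TPTM is read here as a gene's value per 10000000, because every column summed to just under that total (9991842 to 9995581). The scores are therefore normalised and rounded values, not read counts. In every gene the mean of at least 1 organ was 10 TPTM or more, and in 63 genes the highest organ mean was exactly 10, so the authors' table holds only genes at or above that level. Every column of the table matched 1 library by its label. No gene length correction is recorded.

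Rounding hides the reads behind each score, but the low whole numbers were used unevenly, in a pattern that depends on how many reads make 1 TPTM. A likelihood fit of that pattern between 15 and 200 TPTM assuming that each score is a read number scaled to 10000000 and rounded, gave an estimate for 4 of the 6 libraries, where 1 TPTM stood for about 2.18 reads in fruit replicate 2, 3.34 in pedicle replicate 2, 2.42 in stalk replicate 1 and 2.76 in stalk replicate 2. An estimate was kept only where its log likelihood was at least 3 above that of any other depth. Of 100 simulated libraries with depths drawn between 1 and 6 reads per TPTM, 51 met this rule, of which 50 were right. The depths of fruit replicate 1 and pedicle replicate 1 are unknown. Reads could not be recovered gene by gene because more than 1 read total rounds to the same score. For this reason no count model was used, and no counting interval is given for single genes.

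Scores were analysed as log2(TPTM + 5) for the 15381 genes with at least 10 TPTM in at least 2 libraries, and 339 genes were left out by this filter. One linear model with a term per organ was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, 3 residual degrees of freedom and 7.76 prior degrees of freedom). The spread was shared among organs because 2 libraries per organ alone give little information on it. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 15381 genes of each comparison. Log2 fold changes are on the log2(TPTM + 5) scale, which understates the change of genes with low scores, and are given with their standard error. The p-values rest on the spread between the 2 libraries of each organ, pooled over all organs and moderated across genes. That spread was smallest in stalk and largest in pedicle, so these p-values do not measure the spread of only the organs compared. On average over genes, the pooled spread is too small for pedicle against fruit and too large for stalk against fruit. The numbers of genes called in the comparisons are therefore not on one scale.

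The pipeline was tested on simulated libraries with the real gene means and replicate spreads drawn at random from those of the data, in which 200 genes with a mean of at least 20 TPTM were changed in pedicle, 50 at each fold size. For pedicle against fruit, over 15241 simulated genes tested, it called 0 of 50 genes changed 2-fold, 23 of 50 changed 4-fold, 32 of 50 changed 8-fold and 38 of 50 changed 16-fold, with 3 unchanged genes called. For stalk against fruit, where no simulated gene differed, it called 0 genes. Each simulated gene had the same spread in all organs, drawn without regard to its mean, unlike the real libraries. These numbers therefore do not give the rate of false calls in the real data.

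The deposited table identifies genes by locus identifiers only. None of the 15720 identifiers (0 matched) occurs in the RefSeq gene table of 23999 cucumber genes that was used for names, so genes are given by identifier and their products are not stated. The gene lists fixed before the data were examined (phloem and other cell type markers, sugar transport and metabolism, hormones, stress and others) were defined by words in product descriptions. They could not be applied, and the set tests planned on them were not run. Genes named in the text follow the rule set for this case before the data were examined. For each comparison, they are the 2 with the largest log2 fold change in each direction among called genes with at least 50 TPTM in the higher organ and no overlap between the 2 organs' libraries.

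A gene was said to set an organ apart when it was called in the same direction in both comparisons of that organ. Because both comparisons use the same libraries of that organ, 100 data sets without any organ effect were simulated with the fitted spread of each gene. That spread was taken as equal in all organs. The organs share replicate numbers in the labels, but no label ties a number to a shared plant or day, so the numbers were not treated as pairs. Within organs, squared differences between libraries exceeded those of counting noise 22.1 to 36.3 times when 1 TPTM is taken as 1 read, so the 2 libraries of an organ were not the same reads deposited again. This check does not separate biological replicates from repeat amplifications of 1 RNA; that they are biological replicates comes from the design text alone.

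Alternatives were other pseudocounts (1 and 20), no filter and a stricter filter (30 TPTM), quantile normalisation, trimmed-mean (TMM) factors, limma without the trend and with a robust prior, a replicate block, fits of only the 2 organs compared, a minimum change of 2-fold, and leaving out each library in turn. A rescaling of every library without its most abundant genes was added after seeing the data. Figures and permutations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.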

Results

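Gene expression was measured in laser-dissected phloem, the tissue that carries sugars and signals through the plant, from 3 organs of the young cucumber fruit system. The 6 libraries comprised 2 each of pedicle, stalk and fruit, taken 3 days after anthesis. The study set out to find genes expressed and regulated in the phloem of these organs. Scores were normalised by the authors to 10000000 per library (TPTM), and 15381 of the 15720 genes in the table were tested. The median gene had a score of 128 and 133 TPTM in the pedicle libraries, 140 and 131 in the stalk libraries and 143 and 158 in the fruit libraries. Between 13959 and 14856 genes reached 10 TPTM in a library. The 10 most abundant genes of each library took 14.5% and 15.3% of all expression in pedicle, 8.64% and 9.76% in stalk and 10.1% and 9.43% in fruit. Genes listed at 0 numbered 510 and 306 in the pedicle libraries, 89 and 103 in the stalk libraries and 159 and 161 in the fruit libraries.

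Pedicle phloem stood apart from the other organs, and stalk phloem lay closer to fruit than to pedicle. The first principal component held 57.2% of the variance and placed the pedicle libraries at -92.8 and -75.2, the stalk libraries at 23.9 and 24.8 and the fruit libraries at 61.2 and 58.0. The mean correlation of log2 scores across genes was 0.934 between stalk and fruit libraries, 0.890 between pedicle and stalk and 0.848 between pedicle and fruit. All 4 stalk-fruit correlations (0.926 to 0.941) were above all 4 pedicle-stalk correlations (0.880 to 0.904). Replicates correlated at 0.982 in stalk, 0.956 in fruit and 0.941 in pedicle, and their root mean square standard deviation per gene was 0.31, 0.47 and 0.57 on the log2 scale. Of the 15 ways to sort the 6 libraries into pairs, the pairing by organ had the highest mean correlation within pairs, 0.960. Its one-sided exact permutation p of 0.067 is the smallest this design can give.

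**Figure D1:**
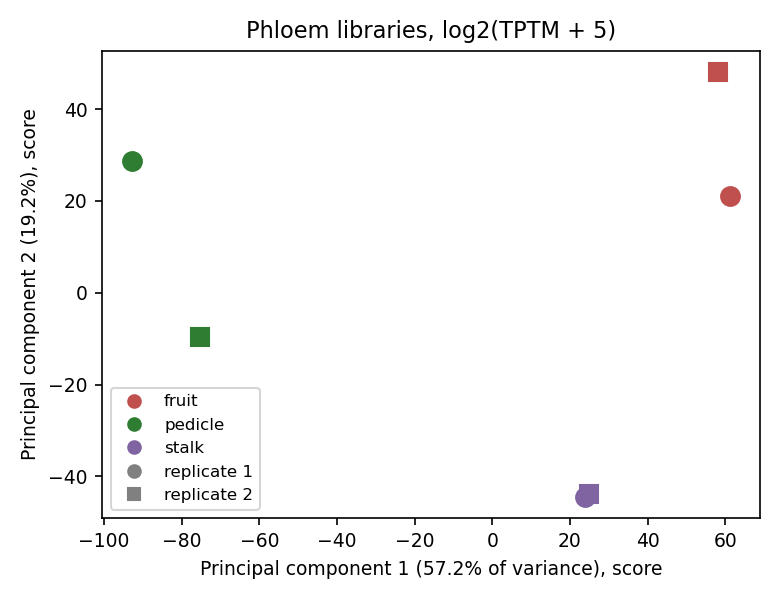
Scores of the 6 phloem libraries on the first 2 principal components of log2(TPTM + 5) over 15381 genes; colours mark organs and symbols mark replicates. The pedicle libraries lie at -92.8 and -75.2 on the first component, and the stalk libraries at 23.9 and 24.8, between pedicle and fruit.

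Pedicle and fruit differed in 3474 genes, 22.6% of those tested (limma over all organs, adjusted p under 0.05). With only these 2 organs in the fit, 2294 genes were called. Of the 3474 genes, 1159 were higher in pedicle and 2315 were higher in fruit, with median log2 differences of 1.63 and -1.66. Changes of at least 10-fold were found in 121 genes higher in pedicle and 196 higher in fruit, and changes of at least 100-fold in 3 and 9 genes. The largest rise toward pedicle was in Csa6G367090, with 4466.5 ± 1610 TPTM in pedicle and 5 ± 1.41 TPTM in fruit (SD, n = 2), a log2 difference of 8.76 ± 0.32 (SE; limma adjusted p = 2.22e-07). Csa6G476020 followed, with 2293.5 ± 333 TPTM in pedicle against 12 and 0 TPTM in the fruit libraries (log2 difference 7.95 ± 0.53, limma adjusted p = 8.28e-06; 8.84 without fruit replicate 1 and 7.07 without fruit replicate 2). In the other direction, Csa4G154320 was at 1 TPTM in both pedicle libraries and at 1702.5 ± 268 TPTM in fruit (log2 difference -8.14 ± 0.35, limma adjusted p = 5.32e-07). Csa4G617410 was at 1.5 ± 0.71 TPTM in pedicle and 1785.5 ± 96.9 TPTM in fruit (log2 difference -8.11 ± 0.34, limma adjusted p = 5.32e-07).

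The genes that differed between pedicle and fruit were spread over all levels of expression. Among genes with a mean under 50 TPTM, 197 were higher in pedicle and 477 lower, and among those of 50 to 500 TPTM, 549 were higher and 1142 lower. Among genes of 500 to 5000 TPTM, 370 were higher and 651 lower, and among those over 5000 TPTM, 43 were higher and 45 lower. Both fruit libraries listed 29 of the genes higher in pedicle at 0, and both pedicle libraries listed 110 of the genes higher in fruit at 0. The 10 most abundant genes called higher in pedicle than in fruit took 10.4% ± 0.20 of pedicle expression (SD, n = 2), 1.92% ± 0.03 of stalk and 1.02% ± 0.30 of fruit. Their log2 differences from fruit ran from 1.67 to 6.48, and 8 of the 10 were also higher in pedicle than in stalk. The 10 most abundant genes called higher in fruit took 5.44% ± 0.60 of fruit expression, 4.23% ± 0.22 of stalk and 2.05% ± 0.23 of pedicle. These differed less between the organs, by 0.96 to 2.66 on the log2 scale, and 5 of the 10 were also lower in pedicle than in stalk. These shares describe genes picked for their difference in the same libraries.

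In all 3474 genes called between pedicle and fruit the 2 organs' libraries did not overlap, which held for 57.9% of all tested genes and would hold for 33.3% by chance with 2 libraries against 2. Genes of 1 library move together and few other splits exist, so the excess over 33.3% is no test of an organ effect. The direction of the calls depended on scaling: 66.6% were lower in pedicle as deposited, 53.1% with TMM factors and 51.2% with quantile normalisation, settings that moved the median log2 difference of all genes, -0.21 as deposited, by 0.17 and 0.22. The count fell to 1811 without fruit replicate 1, 1793 without fruit replicate 2, 2276 without stalk replicate 1, 2264 without stalk replicate 2 and 2294 with only these 2 organs in the fit.

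**Figure D2:**
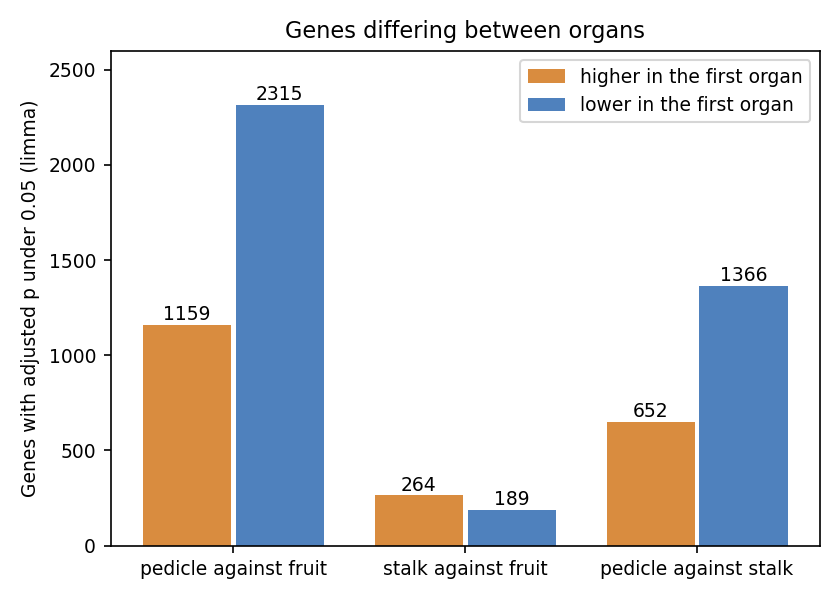
Genes with a limma adjusted p under 0.05 in each comparison of 2 organs, as bars of the number higher and the number lower in the first organ named. Pedicle against fruit has 1159 higher and 2315 lower genes, stalk against fruit 264 and 189, and pedicle against stalk 652 and 1366.

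Stalk and fruit differed in 453 genes, 2.95% of those tested, of which 264 were higher in stalk and 189 were higher in fruit; which direction held more genes depended on the fit. Nearly all of these calls, 263 and 188, were at least 2-fold, and 14 genes higher in stalk and 13 higher in fruit reached 10-fold. The smallest called difference was 0.98 on the log2 scale, so the 2-fold share reflects what the test could call. Csa6G367090 was again the largest rise away from fruit, with 1851 ± 451 TPTM in stalk (SD, n = 2) and a log2 difference of 7.52 ± 0.32 (SE; limma adjusted p = 2.24e-06). Csa5G114560 had 1403 ± 322 TPTM in stalk against 3 and 104 TPTM in the fruit libraries (log2 difference 5.56 ± 0.89, limma adjusted p = 0.0093). Its log2 difference was 3.67 without fruit replicate 1 and 7.44 without fruit replicate 2. In the latter setting it ranked above Csa6G367090, at 7.38. The largest differences toward fruit were in Csa7G336480 and Csa7G336450, whose fruit replicates were far apart. Csa7G336480 had 739 and 72 TPTM in the fruit libraries and 1 and 8 TPTM in the stalk libraries (log2 difference -4.76 ± 0.88, limma adjusted p = 0.019). Csa7G336450 had 348 and 58 TPTM in fruit and 2 and 1 TPTM in stalk (log2 difference -4.52 ± 0.71, limma adjusted p = 0.0086). These last 2 genes were also low in pedicle, at 0 to 2 TPTM. Csa5G114560, Csa7G336480 and Csa7G336450 no longer passed when either stalk library was left out, and their limma adjusted p over all alternatives ranged from 0.0020 to 0.148, 0.011 to 0.254 and 0.0044 to 0.160.

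At an unadjusted limma p under 0.05, 2952 genes passed between stalk and fruit, where 453 passed after adjustment. A share of about 0.05 of the tested genes would pass without any difference. Of tested genes, 54.4% had no overlap between the libraries, against 33.3% by chance. As for pedicle and fruit, this excess is no test of an organ effect. The majority turned toward fruit when only the stalk and fruit libraries were fitted (1000 genes, 453 higher in stalk and 547 in fruit), without pedicle replicate 1 (970 genes, 451 and 519) and without pedicle replicate 2 (977 genes, 450 and 527). The count fell to 133 without the intensity trend, 174 without fruit replicate 1, 80 without fruit replicate 2, 27 without stalk replicate 1 and 33 without stalk replicate 2, and TMM factors, which moved the median difference of all genes by 0.11 from -0.12, gave 326 genes higher in stalk and 140 higher in fruit.

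Pedicle and stalk differed in 2018 genes, 13.1% of those tested, with 652 higher in pedicle and 1366 higher in stalk. Changes of at least 10-fold were found in 55 genes higher in pedicle and 115 higher in stalk. Csa6G476020, one of the genes most raised against fruit, was also the most raised against stalk, where it had 20 ± 2.83 TPTM (SD, n = 2; log2 difference 6.52 ± 0.53 SE, limma adjusted p = 5.18e-05). This rank depended on the setting. Csa7G222870 was raised more with a pseudocount of 20 (6.03 against 5.85) and without stalk replicate 1 (7.73 against 6.40). Csa7G222870 was the most abundant gene named here, with 48864.5 ± 2986 TPTM in pedicle against 2253 and 225 TPTM in the stalk libraries (log2 difference 6.08 ± 0.87, limma adjusted p = 0.0013; from 8.80e-05 to 0.062 over the alternatives, the last with a robust prior). Its log2 difference was 7.73 without stalk replicate 1 and 4.43 without stalk replicate 2. Of the genes higher in stalk, Csa6G516780 had 8.5 ± 2.12 TPTM in pedicle and 1733 ± 25.5 TPTM in stalk (log2 difference -7.02 ± 0.27, limma adjusted p = 6.92e-07). Its level in fruit, 2559.5 ± 336 TPTM, was not distinguished from stalk (log2 difference of stalk from fruit -0.56 ± 0.27, limma adjusted p = 0.29). Csa2G371100 was at 2 TPTM in both pedicle libraries and at 907.5 ± 333 TPTM in stalk (log2 difference -6.98 ± 0.56, limma adjusted p = 4.87e-05).

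Genes called between pedicle and stalk were lower in pedicle in 67.7% of cases as deposited in 57.1% with quantile normalisation and in 57.6% after rescaling without the most abundant genes (chosen after seeing the data), each of which moved the median difference of all genes by 0.11 from -0.07. The count fell to 545 without stalk replicate 1 and 482 without stalk replicate 2.

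**Figure D3:**
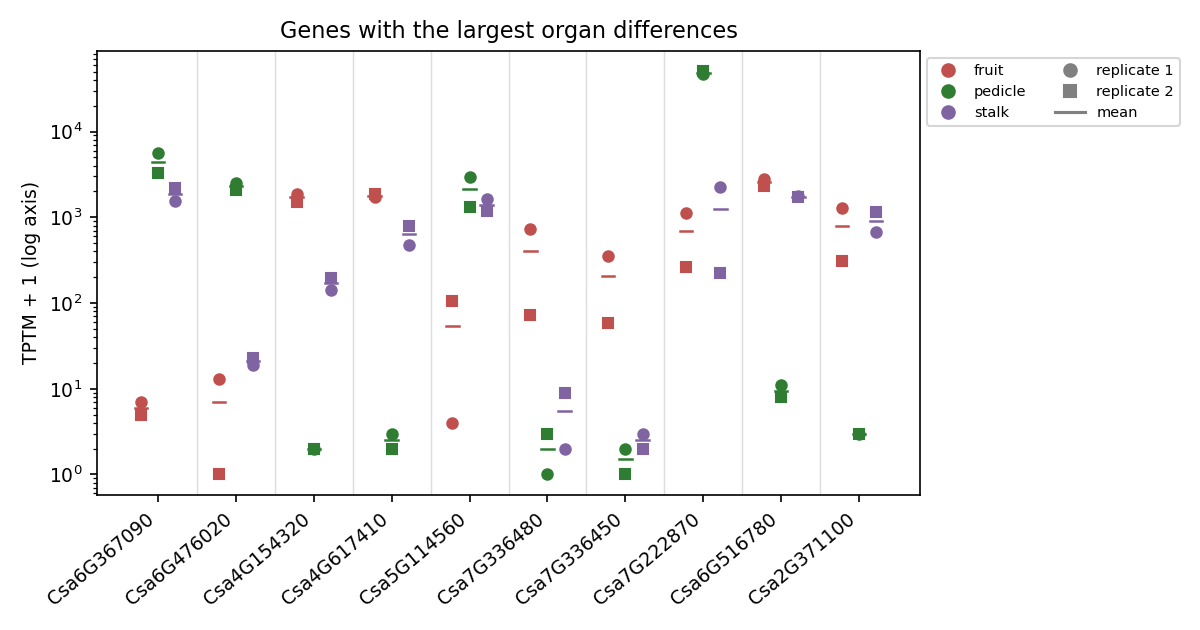
TPTM of the 10 named genes in each library, plotted as TPTM + 1 on a log axis; colours mark organs, symbols replicates and short lines organ means. Csa6G367090 is at 6 and 4 TPTM in fruit against 5605 and 3328 in pedicle, and the replicates of Csa7G336480 in fruit lie at 739 and 72.

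Of the 3 organs, pedicle was set apart from both others by the most genes. Pedicle was higher than both other organs in 451 genes and lower than both in 1015. Fruit was higher than both others in 147 genes and lower in 157, and stalk was higher in 91 and lower in 26. Csa6G476020 and Csa7G222870 were among the genes higher in pedicle than in both other organs, and Csa6G516780 and Csa2G371100 among those lower. Csa6G367090 was lower in fruit than in both others, and it was also higher in pedicle than in stalk (log2 difference 1.24 ± 0.32, limma adjusted p = 0.029). Csa4G154320 and Csa4G617410 fell stepwise from fruit to stalk to pedicle. Csa4G154320 had 169 ± 38.2 TPTM in stalk (SD, n = 2; limma adjusted p = 0.0015 against fruit and 2.96e-05 against pedicle). Csa4G617410 had 637 ± 229 TPTM in stalk (limma adjusted p = 0.041 against fruit and 4.83e-06 against pedicle). In all, 27 genes took this stepwise course and 30 the opposite one, from pedicle down through stalk to fruit, where independent lists of these sizes would share 16.8 and 11.2. Both comparisons use the stalk libraries, so the lists are not independent, and these counts were not followed over the alternatives.

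The 2 comparisons of an organ share its libraries, so some overlap between them arises without any effect. In 100 simulated data sets with no organ effect, at most 1 gene passed both comparisons of any organ in the same direction. Hardly any gene is called in such data, so this value does not show how much the shared libraries add to lists of the observed sizes. Independent lists of the observed sizes would share 49.1 genes higher and 206 lower in pedicle, 28.4 higher and 19.9 lower in fruit, and 23.4 higher and 8.01 lower in stalk. The covariance of the log2 differences of an organ from the other two was 0.890 for pedicle, 0.437 for fruit and 0.069 for stalk, where shared libraries alone gave a mean of 0.0876 to 0.0879 in the simulations. The correlations were 0.789, 0.533 and 0.099, against means of 0.499 to 0.501 in the simulations. The simulations gave every organ the same spread, but the replicates' standard deviation was 0.57 in pedicle, 0.47 in fruit and 0.31 in stalk. Both simulated values are therefore too low for pedicle and fruit and too high for stalk, and do not place stalk below the shared part. Nor does the correlation of 0.533 place fruit above it. With 1 library of an organ set against each of the other organs, so that none was shared, the covariance was 0.701 to 0.755 for pedicle, 0.281 to 0.375 for fruit and 0.0105 to 0.0364 for stalk over both assignments. The called lists were not split in this way, and part of the excess in their overlap may come from the shared libraries. The genes that set fruit apart, 304 in all, numbered 115 without fruit replicate 1, 60 without fruit replicate 2, 567 without pedicle replicate 1, 509 without pedicle replicate 2, 21 without stalk replicate 1 and 25 without stalk replicate 2. Those of stalk, 117 in all, numbered 59 and 26 without fruit replicates 1 and 2, 229 without pedicle replicate 2, and 6 and 8 without stalk replicates 1 and 2. Those of pedicle, 1466 in all, numbered 894 without fruit replicate 1, 466 without stalk replicate 1 and 417 without stalk replicate 2. The total of 1887 genes that set an organ apart fell to 1068 without fruit replicate 1, 1114 without fruit replicate 2, 493 without stalk replicate 1 and 450 without stalk replicate 2.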

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

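No gene called as reported was called in the opposite direction under any alternative (the direction of calls that were lost was not counted), and the counts for each comparison stayed within 1.5 times the reported ones except in the cases given here. Fitting only the 2 organs compared gave 2294 genes between pedicle and fruit (3474 as reported) and 1000 between stalk and fruit (453), and dropping the intensity trend gave 133 between stalk and fruit. Leaving out 1 library in turn gave 1793 to 3685 genes between pedicle and fruit, 27 to 977 between stalk and fruit, 482 to 2610 between pedicle and stalk (2018 as reported), and 450 to 2585 that set an organ apart (1887 as reported). Such fits have fewer libraries, and the lone library left in an organ is assumed to vary like the others. The stalk libraries had the smallest spread and entered the shared estimate. By organ, the genes set apart numbered 417 to 1847 for pedicle, 21 to 567 for fruit and 6 to 229 for stalk with 1 library left out. They numbered 106 for fruit and 30 for stalk without the trend, and 484 and 184 with only the organs compared; for these changes the cause was not tested. With the replicate number as a replicate block, the counts were 3105, 337 and 1778, all within 1.5 times those reported. Differences between replicates 1 and 2 correlated across genes at -0.0487 between pedicle and fruit, 0.0103 between stalk and fruit and -0.117 between pedicle and stalk. These values give no sign of pairing by number. With 1 difference per organ, they cannot exclude a shared plant or day whose effect is small. Over the alternatives, the 12 fold changes by which genes were named kept their direction and their call in 202 of 212 cases and lost the call in 10. Other comparisons given for these genes were not followed over the alternatives. They include the stalk steps of Csa4G154320 and Csa4G617410, and Csa6G367090 between pedicle and stalk. The size of a fold change depended on the pseudocount, which moved 11 of the 12 by more than 1.5 times (by up to 1.79 on the log2 scale), and quantile normalisation gave -7.56 for Csa4G154320 and -7.50 for Csa4G617410 between pedicle and fruit. The lost calls were those of Csa5G114560, Csa7G336480, Csa7G336450 and Csa7G222870 named in the results, together with Csa5G114560 at an adjusted p of 0.070 and Csa7G336480 at 0.074 without the trend, and Csa5G114560 at 0.119 with a robust prior. Csa7G336480 and Csa7G336450 were below the filter when either fruit library was left out and have no value there. The 2 tests planned on read counts were not run, because whole reads could not be recovered, nor were the gene list tests, because no identifier matched a name. With 2 libraries per organ there are too few libraries for a count over other splits. In simulated data, 0 of 50 genes changed 2-fold were called between pedicle and fruit. That share does not give the power in the real data, where log2 differences down to 0.68 were called. A small change that was not called is still not shown to be absent. Depth was estimated for 4 of the 6 libraries only.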

Other observations

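The comparison of library correlations, the rescaling without the most abundant genes, the test of genes under 500 TPTM and the tests by abundance under other scalings were chosen after seeing the data.

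Among the 3474 genes that differed between pedicle and fruit, stalk lay at a median of 0.35 of the way from fruit to pedicle on the log2 scale (quartiles 0.11 and 0.59), and 67.0% of the genes were nearer to their fruit level in stalk. In 738 of them stalk lay outside the range of the other organs. Genes chosen for a difference between pedicle and fruit lie partly by chance at the ends of that range, so the position of stalk is a description only. The share of genes called was lowest among scarce genes. Between stalk and fruit it was 0.94% under 50 TPTM, 2.25% at 50 to 500 TPTM, 6.70% at 500 to 5000 TPTM and 7.5% above, and between pedicle and fruit it was 17.6% and 20.9% in the lower classes and at least 31.4% in each of the upper ones. Among stalk-fruit calls in genes over 5000 TPTM, 17 were higher in stalk and 4 in fruit.

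More genes were lower than higher in pedicle against fruit as deposited (2315 and 1159), but this excess depended on scaling. The share lower was 53.1% with TMM factors (interval 51.4% to 54.8%) and 51.2% with quantile normalisation (interval 49.5% to 52.9%). These intervals, like those below, take genes as independent, which genes of the same libraries are not. Both settings moved the median log2 difference of all genes, from -0.21 as deposited to -0.035 and 0.0077. Such a move evens the split by itself, so these shares cannot show whether the excess is real or which scaling is right. A larger share of pedicle expression taken by a few abundant genes stays open: the 39 genes among the 20 most abundant of any library took at least 23.3% of each pedicle library and 16.1% to 17.7% of the others, and rescaling without them left 57.7% lower (interval 56.0% to 59.4%), between the bounds of 55% and 60% set before that result was seen. Loss of scarce transcripts in the pedicle libraries stays open too, since the share among called genes with a mean of at least 500 TPTM was 62.8% as deposited (exact 95% interval 59.8% to 65.6%), over the bound of 55% set before it was seen, but 47.3% with TMM factors, 52.3% with quantile normalisation and 52.8% after the rescaling. Under 500 TPTM 68.5% of called genes were lower as deposited (interval 66.5% to 70.3%), 55.7% with TMM factors, 1336 of 2225 after the rescaling and 50.6% with quantile normalisation, below the share in the abundant genes only with the last, and pedicle listed 207 genes at 0 in both libraries and 402 in 1, against 61 and 198 in fruit and 59 and 74 in stalk. Neither explanation can be excluded, and an organ difference, which was not tested separately, stays open as well.

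Pedicle phloem differed from stalk in more genes than stalk did from fruit (2018 and 453). With only the 2 organs compared in the fit the numbers were 1783 and 1000, so the size of this gap depends on which organs enter the fit. Both pedicle libraries correlated less with stalk libraries (at most 0.904) than stalk did with fruit (at least 0.926). Replicates correlated at 0.941 in pedicle and 0.982 in stalk, and noisier libraries correlate less with any other. This comparison, chosen after seeing the data, therefore does not settle whether 1 pedicle library is aberrant. The smaller ratio of the 2 counts with a pedicle library left out was 1.53, between the bounds of 1 and 2 set before it was seen, and so does not decide. In the fit of all organs, a few abundant genes are argued against as the whole cause, since the ratio was 4.14 after rescaling without them. The rescaling was not combined with fits of only the 2 organs compared, where the gap was smaller. A difference between organs, or between the cell types dissected from them, stays open without a test, as do RNA quality, amplification and preparation day, which the labels do not give by library.

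Genes next to each other in identifier order were called in the same direction more often than in random orders. Of 15373 neighbouring pairs of tested genes, 578 were called in the same direction between pedicle and fruit, against a mean of 434.8 and a highest value of 503 in 10000 random orders within chromosome prefixes (permutation p = 0.0001, the smallest these orders can give). The numbers were 24 against a mean of 6.73 between stalk and fruit and 236 against 149.6 between pedicle and stalk, each above all random orders, while pairs of opposite direction between pedicle and fruit, 301, lay within the random range of 290 to 405. This is consistent with neighbouring genes sharing an organ preference, a hypothesis, if identifiers follow the order of genes on the chromosome, which was not checked here. Reads shared between near-identical neighbours cannot be told apart from this: the replicate deviations of the 578 pairs correlated at 0.116, above the highest of 1000 sets of random pairs, 0.082, which either explanation could give.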
